A study of Homo sapiens with 12 samples.

How the data were processed

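The 12 RNA-seq libraries came from 4 groups of 3, control and transduced cultures of a human induced pluripotent stem cell line at stage 5 and stage 6 of differentiation toward beta cells. Per the labels' protocols, total RNA was isolated with a column kit and libraries were prepared with standard Illumina protocols. Per the submitters' processing notes, Bowtie 0.12.2 was among the tools and mm8, a mouse build, was the genome build, whereas the deposited tables carry human Ensembl gene identifiers. The counting tool, the annotation release, the strand setting, the human genome build and any filter on low values are not given in the sources used here. A wrong or unspliced alignment would change the counts of single genes, and without a known strand setting overlapping and antisense genes cannot be told apart.

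The deposited values were whole-number counts per gene and library, judged from the values and the file headers, in 4 tables of 17035 genes, each holding 2 groups. Each library stood in 2 tables, with identical counts in all 12 cases, and no per-library column was left unused. The lowest count was 16, and each gene lay above 1 CPM in at least 10 libraries and 16433 genes in all 12, so genes of lower or more restricted expression were not analysed here. MAFA was not analysed here either, and no level is given for it. Beside the counts, the authors' tables gave a log2 fold change, a mean log2 CPM, a p-value and a false discovery rate per gene, per the file headers. The authors' log2 fold changes of the stage comparisons run from stage 6 to stage 5, judged against the counts, and were turned round here. Lists of 30 top genes picked by the submitters were not used, because the full tables hold the same comparisons.

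Of the gene identifiers, 16380 matched a current gene symbol, and 25 gene names had been deposited as dates, of which 24 were resolved by identifier. Symbols that occur more than once (52 entries) were not named. Only 765 of 16458 gene starts lay within 1000 bases of their position in the GRCh38 annotation, so coordinates are given as the authors' tables give them and no position was taken from that annotation.

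Counts were normalised by TMM and fitted with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood method, with 1 fit of all 12 libraries, a group factor and no further covariate. The low-count filter (filterByExpr, minimum count 10) removed 0 genes. The common biological coefficient of variation was 0.112 and the prior degrees of freedom 4.18. The contrasts were transduced against control at stage 5 and at stage 6, stage 6 against stage 5 in controls and in transduced cultures, and the interaction, which is the transduction effect at stage 6 minus that at stage 5. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were computed as the size of the log2 fold change over the square root of the F statistic. Group levels are means and SDs of CPM with TMM-adjusted library sizes, and principal components used log2 CPM with a prior count of 2.

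Gene lists were fixed before the data were examined. They held the transduced factors, beta cell identity, hormone granule and exocytosis, glucose sensing and excitability, other islet hormones and their regulators, endocrine progenitors and NEUROG3 targets, pancreatic progenitor and duct, acinar, pluripotency, liver, intestine and stomach, enterochromaffin-like, mesenchyme, neural, endothelial, proliferation, interferon and viral response, endoplasmic reticulum stress, genes usually kept low in beta cells, the Notch pathway, p53 response and apoptosis, and inflammatory signalling. The 20 lists with more than 2 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a comparison. With an estimated correlation camera called 0 of the 20 lists in each comparison. At an unadjusted p under 0.05 it then had 5 lists up at stage 5, 1 up at stage 6, 1 up and 1 down in controls, 2 down in transduced cultures, and 1 up and 4 down in the interaction. Fisher's exact test (two-sided, adjusted) of called members called 6 up and 5 down, 4 and 5, 3 and 1, 2 and 1, and 0 and 6 of these 20 lists in the same order.

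Genes were named by a rule fixed before the data were examined. It took the transduced factors, INS, GCG and SST in each comparison, the 10 largest rises and 10 largest falls in log2 fold change among called genes averaging at least 5 CPM in the higher group in each transduction comparison, the 5 and 5 in each stage comparison, and the members with the smallest adjusted p of each list. Y-linked genes, XIST and repeated symbols were left out. Some genes taken by the rule, and some members of small counts, are not reported here by name, while the counts include them.

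The fits were tested on simulated counts for the 17035 genes with changes of known size. For 1.5-, 2- and 4-fold changes edgeR recovered 56.7%, 94.0% and 100% at stage 5 with 11 false calls, 71.6%, 94.0% and 100% at stage 6 with 6, and 38.8%, 74.6% and 100% in the interaction with 3. In controls it recovered 64.2%, 95.5% and 100% with 8 false calls, and in transduced cultures 77.6%, 94.0% and 100% with 8. DESeq2 made 44 false calls at stage 5 and 38 in the interaction. Replicates of a group differed by far more than sampling noise, with chi-square per degree of freedom between 18.5 and 102, so none was counted as a duplicate. With 86.7 to 114.3 M counts per library, depth limited mainly genes near the floor of the tables.

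The replicate numbers were checked by correlating the deviations of libraries from their group means. At stage 5 all 3 same-numbered pairs of a control and a transduced library correlated (0.178 to 0.236), against -0.198 to 0.0509 in the 6 other pairs. Equal numbers were thus taken to pair the stage 5 libraries, a pairing from the data and not the labels. It is uncertain, as a full matching of unequal numbers between the transduced groups had 0.177 to 0.245, and a stage 6 pair 0.269. Results with a block within stage 5 rest on it. In each of the 3 other comparisons 0 of 3 same-numbered pairs lay over 0.1, so the numbers there were treated as names only.

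Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors and its Wald test, no low-count filter, a fit of only the groups compared, the replicate number as a block, each library left out, an adjusted p threshold of 0.01, a 2-fold size threshold, and for lists the estimated correlation and Fisher's exact test. Further alternatives and 9 further gene lists were chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.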

Results

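RNA was sequenced from cultures of the human induced pluripotent stem cell line IISH2i-BM9 that were taken stepwise toward pancreatic beta cells, the insulin-secreting cells of the islet. Per the labels' protocols, transduced cultures received the transcription factor genes PDX1 at stage 1, NGN3 (gene symbol NEUROG3) at stage 4 and MAFA at stage 6. The 12 libraries formed 4 groups of 3, namely control and transduced cultures at stage 5 and at stage 6. Both transduced groups carry the treatment label PNM, whereas the series' design text names PN-treated as well as PNM-treated cells, so both groups are called transduced here. An empty-vector arm was not analysed here. Total gene counts were 96.2 ± 8.42 M (mean ± SD, n = 3) in stage 5 controls and 106.6 ± 9.54 M in stage 5 transduced cultures. At stage 6 they were 92.8 ± 7.39 M in controls and 102.9 ± 8.91 M in transduced cultures, and single libraries held between 86.7 and 114.3 M. Mitochondrial genes took 1.22% to 1.58% of the counts of a library. Since the labels do not say that replicates were separate cultures, p-values measure only the spread between these libraries, which may be technical.

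The libraries of each group lay together in a principal component analysis of log2 CPM (counts scaled to a common library size). The first component, with 58.6% of the variance, ran from -55.4 to -9.87 in stage 5 libraries and from 21.4 to 49.0 in stage 6 libraries. Within each stage transduced libraries lay higher on this component than controls. On the second, with 24.6%, controls lay between 16.3 and 37.5 and transduced libraries between -43.3 and -7.56. Gene levels below are group means ± SD in CPM with n = 3 per group, and log2 fold changes are given ± SE. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 17035 genes, and those of gene lists from limma's camera test. A gene is called where its adjusted p lay under 0.05. Members of gene lists that are named without a value were chosen after their values were seen.

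**Figure D1:**
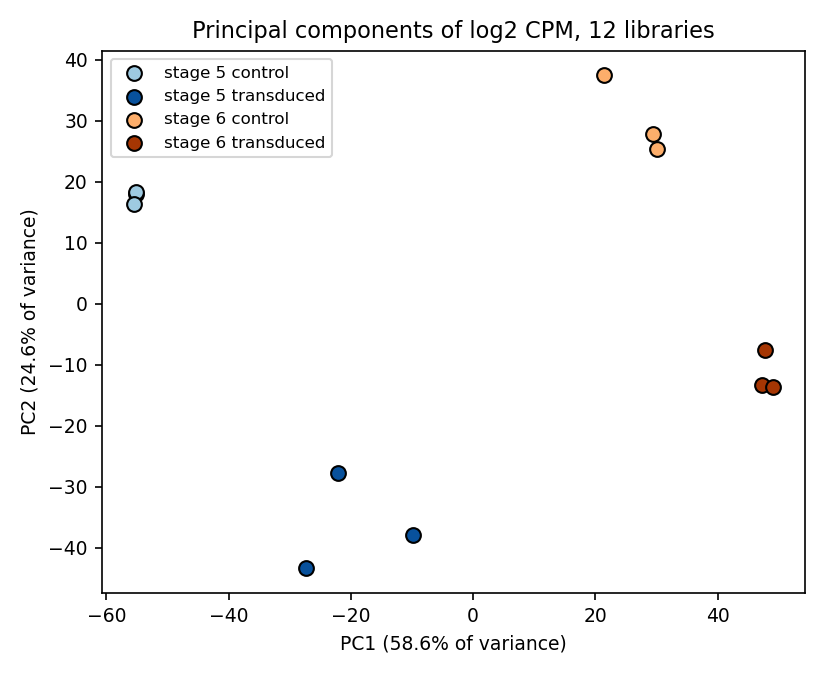
Principal components of log2 CPM over the 12 libraries, with 1 point per library coloured by group. The horizontal axis (58.6% of the variance) separates the stages, and within each stage transduced libraries also lie further right than controls. The vertical axis (24.6%) separates control from transduced libraries.

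The stage 5 comparison asked how transduction changed the cultures by that stage. Among the transduced factors, PDX1, a regulator of pancreas formation and of the insulin gene, averaged 15.9 ± 8.53 CPM in transduced and 3.19 ± 0.518 CPM in control libraries (log2 fold change 2.32 ± 0.39, adjusted p = 8.25e-04). NEUROG3, which starts endocrine differentiation in the pancreas, averaged 5.32 ± 3.06 against 1.39 ± 0.287 CPM (1.93 ± 0.41, adjusted p = 0.00382). Both measured members of this list rose, and both were called when adjusted over the list alone. MAFA was not analysed here, and counts per gene do not tell vector transcripts from endogenous ones. In the authors' table, for which no human genome build is given in the sources used here, PDX1 (ENSG00000139515) lies on chromosome 13 from 28494157 to 28500368, and NEUROG3 (ENSG00000122859) on chromosome 10 from 71331454 to 71332994.

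Transcripts of islet hormones and of hormone granules rose together at stage 5. Counts of whole cultures do not tell whether islet or other cells, such as neurons, held them. Insulin (INS, ENSG00000254647, chromosome 11, 2181009 to 2182571) went from 4.52 ± 3.98 CPM in controls to 155 ± 88.5 CPM, a 34.2-fold rise (log2 fold change 5.09 ± 0.62, adjusted p = 9.04e-05). Glucagon (GCG, ENSG00000115263) went from 5.67 ± 4.27 to 75.2 ± 35 CPM (3.72 ± 0.52, adjusted p = 2.42e-04). Somatostatin (SST, ENSG00000157005, chromosome 3, 187386694 to 187388187) went from 33.8 ± 5.09 to 236 ± 18.2 CPM (2.81 ± 0.14, adjusted p = 6.58e-07). Without control replicate 3 the changes of INS and GCG were 6.08 and 4.51. INS overlaps the readthrough gene INS-IGF2, which rose by 1.53 ± 0.28 (named after its values were seen), so the division of reads between them is uncertain.

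INS had the largest rise among called genes that averaged at least 5 CPM in the higher group. It was followed by SCG2 (5.06 ± 0.35, adjusted p = 1.77e-06), a granin of hormone granules, BHLHE22 (4.97 ± 0.40), a neuronal transcription factor, and CHGA (4.74 ± 0.51), the granule protein chromogranin A, which averaged 1514 ± 908 CPM. SCGN (4.60 ± 0.41), the islet transcription factor gene NKX2-2 (4.34 ± 0.40), the glycine transporter gene SLC6A5 (4.26 ± 0.25), SYNPO (4.22 ± 0.35), CRYBA2 (4.18 ± 0.50) and PCSK1 (4.03 ± 0.37), which cleaves proinsulin, completed the 10 largest rises. The largest fall was that of AFP, the fetal liver protein alpha-fetoprotein, from 19.6 ± 10.6 to 1.64 ± 0.513 CPM (-3.58 ± 0.83, adjusted p = 0.00655). After it came CEMIP (-3.46 ± 0.34), the interferon-induced gene IFIT1 (-2.94 ± 0.38), CSMD1 (-2.70 ± 0.25), COLEC12 (-2.61 ± 0.28), FGG (-2.51 ± 0.35), SLC2A2 (-2.46 ± 0.41), SPHKAP (-2.42 ± 0.36), NFIA (-2.40 ± 0.31) and FGB (-2.33 ± 0.38). FGG and FGB encode fibrinogen chains made in the liver, and SLC2A2 encodes a glucose transporter of liver and islet.

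Among the lists fixed before the data were examined, all 21 hormone granule and exocytosis genes rose at stage 5, and 21 rose when adjusted over the list alone (camera adjusted p = 1.19e-33). Examples were CADPS (2.58 ± 0.20) and PCSK2 (1.97 ± 0.16), the second proinsulin-cleaving enzyme. This list had adjusted p = 0.0685 with an estimated correlation. Of 12 beta cell identity genes, 9 rose, 1 fell and 2 were not called, with 10 up and 1 down when adjusted over the list alone (adjusted p = 1.41e-13). NKX6-1 (3.79 ± 0.30), a beta cell transcription factor gene, ISL1 (1.76 ± 0.13) and NPTX2 (1.38 ± 0.07) were among the risers, and the list had adjusted p = 0.0685 with an estimated correlation. Glucose sensing and excitability genes gave 10 up, 1 down and 2 not called of 13, with 11 up and 1 down adjusted over the list alone (adjusted p = 2.13e-05). The potassium channel subunit gene ABCC8 (2.46 ± 0.31) rose while SLC2A2 fell, and the list had adjusted p = 0.194 with an estimated correlation. Other islet hormones and their regulators included 7 risers, 1 faller (HHEX) and 2 not called of 10, with 8 up and 1 down adjusted over the list alone (adjusted p = 8.53e-06). ETV1 (0.90 ± 0.11) rose beside GCG and SST, and this list too had adjusted p = 0.0685 with an estimated correlation. Endocrine progenitor genes and NEUROG3 targets rose for 6 of 13 and 7 were not called, with 7 up adjusted over the list alone (adjusted p = 4.44e-05). NEUROD1 (2.13 ± 0.22), INSM1 (1.51 ± 0.15) and ST18 (2.17 ± 0.17) rose, and the list had adjusted p = 0.0685 with an estimated correlation.

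Markers of other cell types moved along with the islet genes at stage 5. Of 13 neural genes, 10 rose, 1 (OTX2) fell and 2 were not called, with 11 up and 1 down adjusted over the list alone (adjusted p = 5.96e-06), and the list had adjusted p = 0.261 with an estimated correlation. ELAVL4 (1.67 ± 0.15), STMN2 (1.57 ± 0.19) and DCX (1.32 ± 0.14), all neuronal genes, were examples. Liver genes fell for 6 of 11 and 5 were not called, with 6 down adjusted over the list alone (adjusted p = 0.00186), and FGA fell by 1.75 on the log2 scale beside FGB and FGG. That list had adjusted p = 0.488 with an estimated correlation, and lost its call without transduced replicate 2 (adjusted p = 0.0612). Intestine and stomach genes fell for 4 of 7 with 3 not called and 5 down adjusted over the list alone (adjusted p = 0.00422, and adjusted p = 0.362 with an estimated correlation), namely CDX2 (-1.5 ± 0.35), CLDN18 (-1.37 ± 0.26), CDX1 and SOX21. Pancreatic progenitor and duct genes gave 2 up, 7 down and 7 not called of 16, with 2 up and 8 down adjusted over the list alone (adjusted p = 0.0446). PROX1 (1.52 ± 0.11) and ONECUT2 rose and FOXA1 (-1.51 ± 0.22) and HES1 (-0.97 ± 0.08) fell. The list had adjusted p = 0.488 with an estimated correlation, and its call was lost without control replicate 1 (0.0757), control replicate 3 (0.0832) or transduced replicate 2 (0.276) and with DESeq2's size factors (0.054). Both measured acinar genes fell, 2 also when adjusted over the list alone, a list too small for camera. PRSS1 fell from 11.4 ± 2.18 to 2.34 ± 0.895 CPM (-2.29 ± 0.24, adjusted p = 2.8e-05) and is uncertain because near-identical trypsinogen genes can share its reads. CEL (-0.52 ± 0.18, adjusted p = 0.0495) lost its call without control replicate 1 (-0.47, adjusted p = 0.134), control replicate 3 (-0.44, 0.142), transduced replicate 2 (-0.57, 0.0684) or transduced replicate 3 (-0.46, 0.123), in a fit of these 6 libraries alone (-0.53, 0.0967) and with the replicate number as a block within stage 5 (-0.51, 0.0543).

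Lists of stress responses were also tested at stage 5. Endoplasmic reticulum stress genes gave 1 up (DNAJB9), 6 down and 8 not called of 15, the same counts when adjusted over the list alone (adjusted p = 0.0355), with HSP90B1 (-0.41 ± 0.07) and DNAJC3 (-0.34 ± 0.07) as examples. This list had adjusted p = 0.488 with an estimated correlation, and was not called without control replicate 1 (0.088) or transduced replicate 2 (0.0924). The p53 response and apoptosis list had 1 up and 4 down (MDM2, -0.69 ± 0.07, with SESN2, ZMAT3 and BCL2L1) of 14, equally so when adjusted over the list alone (adjusted p = 0.0183, and adjusted p = 0.513 with an estimated correlation). Its call was lost without control replicate 1 (0.05) or transduced replicate 3 (0.0848) and with Fisher's exact test (0.122). No call was made for the enterochromaffin-like list (3 up, TPH1 at 3.98 ± 0.57, DDC at 3.09 ± 0.37 and ADRA2A, and 1 down, LMX1A, of 6) or the mesenchyme list (6 up, with COL3A1 at 2.60 ± 0.42 and TWIST1 at 1.75 ± 0.35, and 4 down, COL1A2, PDGFRA, PDGFRB and TAGLN, of 16). The endothelial list was not called either (1 up, CLDN5, and 2 down, KDR at -1.73 ± 0.21 and TIE1 at -0.63 ± 0.14, of 5). Adjusted over the list alone these counts were 3 and 1, 9 and 4, and 1 and 2. The enterochromaffin-like list was called without control replicate 3 (adjusted p = 0.0427) or transduced replicate 2 (0.000426) and with the replicate number as a block within stage 5 (0.0364), and the mesenchyme list without transduced replicate 3 (0.00503). TPH1 stood at 3.33 without transduced replicate 3 and COL3A1 at 1.94 without transduced replicate 1. Pluripotency genes were not called as a list (2 up, DNMT3B at 0.27 ± 0.06 and LIN28B, and 2 down, ZFP42 at -1.51 ± 0.19 and SOX2, of 10). Neither was the list of genes usually kept low in beta cells called (3 up, OAT at 0.62 ± 0.07, HK1 and ACOT7, and 5 down, REST at -0.57 ± 0.07, SLC16A1, PDGFRA, SMAD3 and MGST1, of 12), nor the Notch pathway (3 up, DLL4 at 1.35 ± 0.13, JAG1 and HEYL, and 3 down, HES1, NOTCH2 and NOTCH3, of 15). Adjusted over the list alone these were 2 and 2, 3 and 5, and 7 and 3. Fisher's exact test called the list of genes usually kept low in beta cells (adjusted p = 0.0215). Interferon and viral response genes fell for 2 of 8, IFIT1 and MX1, and inflammatory genes for 1 of 4, ICAM1, counts that were equal when adjusted over the list alone, and neither list was called. MX1 (-0.72 ± 0.24, adjusted p = 0.0424) and ICAM1 (-0.72 ± 0.23, adjusted p = 0.0312) each lost the call in 4 of 6 fits that left out 1 library. MX1 did so without control replicate 1 (-0.78, adjusted p = 0.0633), control replicate 3 (-0.60, 0.129), transduced replicate 1 (-0.81, 0.0518) and transduced replicate 2 (-0.49, 0.0772), and also in a fit of these 6 libraries alone (-0.73, 0.11). ICAM1 did so without control replicate 1 (-0.68, 0.0818), control replicate 2 (-0.68, 0.0746), transduced replicate 1 (-0.67, 0.0834) and transduced replicate 2 (-0.75, 0.057). LIF was called without transduced replicate 1 (-0.65, adjusted p = 0.0305). Of 20 proliferation genes edgeR called 0, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2, although RRM2 was called without transduced replicate 3 (0.28, adjusted p = 0.0314). In the pluripotency, proliferation and interferon lists the sign of the median (0.17, 0.02 and 0.07) was opposite to the direction of the camera test.

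At stage 5, 4915 genes were called, 2801 higher and 2114 lower in transduced cultures, of which 717 and 295 differed by at least 2-fold. The authors' deposited table gave 2853 and 2188 at its own false discovery rate under 0.05. With an adjusted p under 0.01 the counts were 1788 and 1125. The balance turned round in 4 of 6 fits that left out 1 library, with 2054 and 2190 without control replicate 2, 1875 and 2045 without 3, 2244 and 2424 without transduced replicate 2, and 2027 and 2203 without 3. Fits of 6 libraries alone gave 2076 and 1584 here and 2813 and 2750 at stage 6. The similar total at stage 6 (4925) rests on the joint fit.

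**Figure D2:**
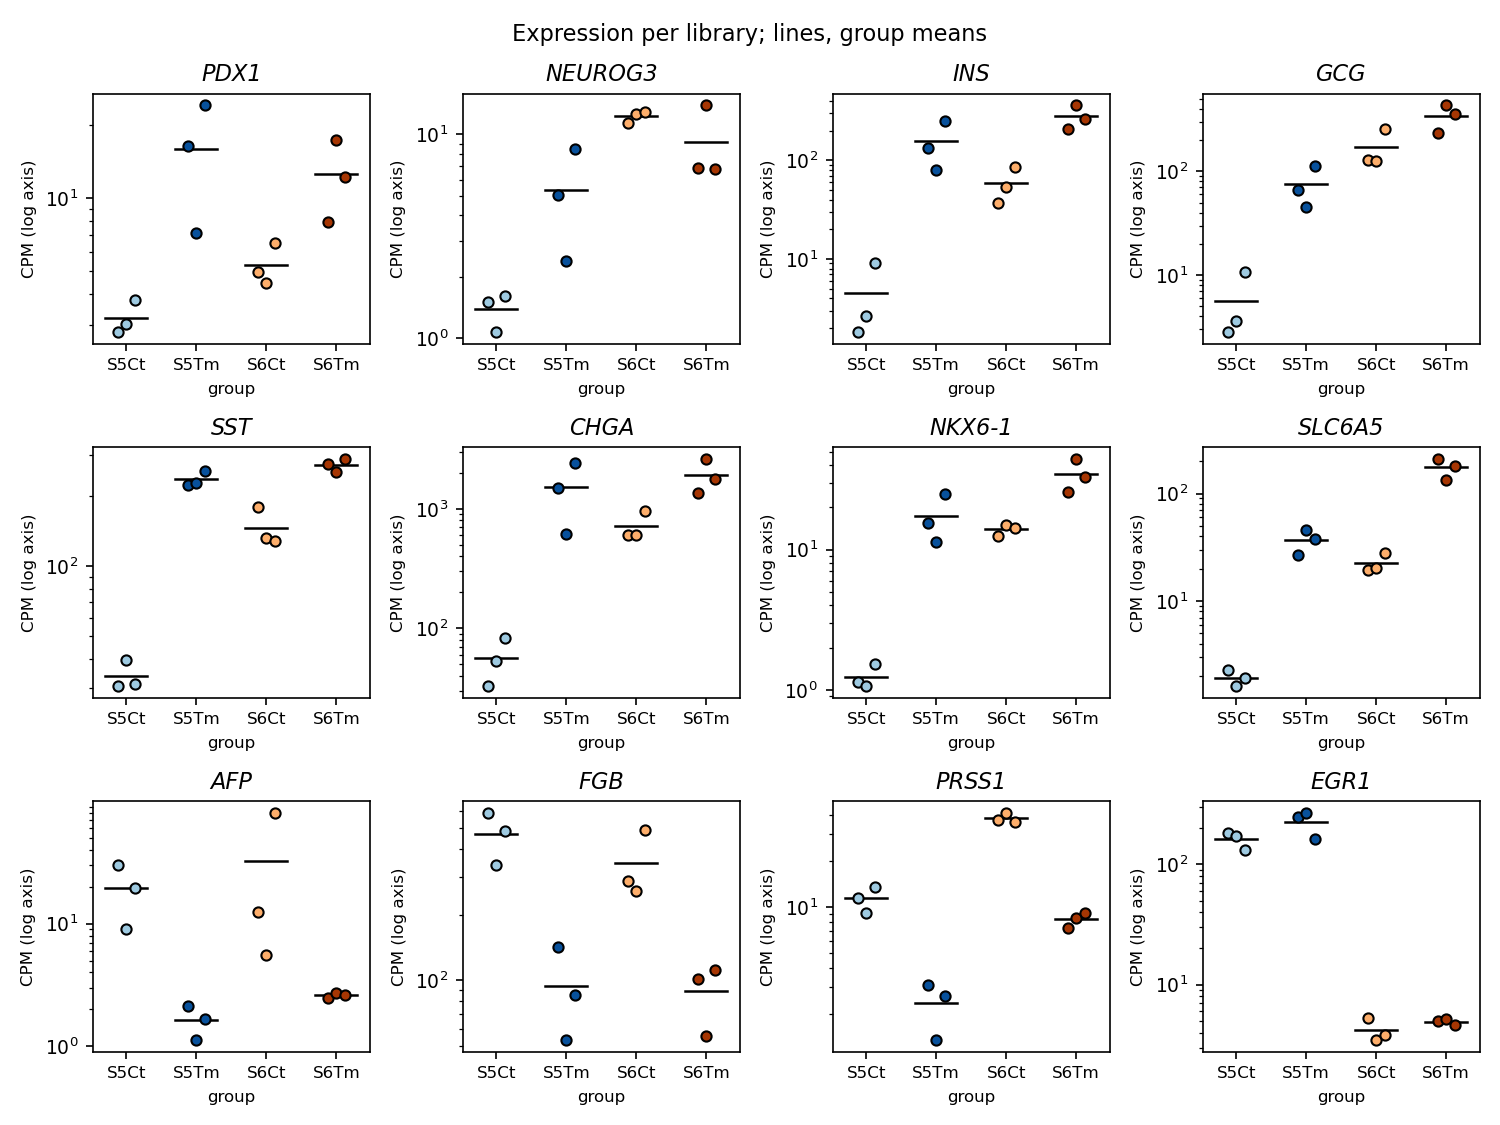
CPM on log axes of 12 named genes in each library, grouped as stage 5 control (S5Ct), stage 5 transduced (S5Tm), stage 6 control (S6Ct) and stage 6 transduced (S6Tm), with horizontal lines at the group means. INS, GCG, SST, CHGA, NKX6-1 and SLC6A5 lie lowest in stage 5 controls, AFP, FGB and PRSS1 lie lower in transduced than in control libraries at each stage, and EGR1 drops at stage 6 in both arms.

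At stage 6 the same question was asked of cultures further along the protocol. As MAFA is given at stage 6 and the labels leave open which factors the stage 5 cultures had received, the factors may differ between the stages. PDX1 averaged 12.5 ± 4.72 CPM in transduced and 5.3 ± 1.06 CPM in control libraries (1.24 ± 0.37, adjusted p = 0.0263). Its call was lost without control replicate 1 (1.2, adjusted p = 0.0753), control replicate 2 (1.13, 0.0981), transduced replicate 2 (0.93, 0.112) or transduced replicate 3 (1.26, 0.0539). NEUROG3 did not pass the test, with 9.19 ± 4.11 CPM against 12.3 ± 0.798 CPM (-0.41 ± 0.37, adjusted p = 0.435), so 1 of 2 measured transduced factors rose, and 1 when adjusted over the list alone. INS rose from 58.9 ± 24.8 to 279 ± 79.5 CPM, a 4.74-fold difference (2.25 ± 0.53, adjusted p = 0.0085), and SST from 147 ± 28.4 to 274 ± 17.2 CPM (0.90 ± 0.13, adjusted p = 5.51e-04). GCG, at 170.5 ± 74.1 CPM in controls and 344 ± 103 CPM in transduced cultures, was not called (1.01 ± 0.46, adjusted p = 0.117), although a fit of these 6 libraries alone called it (adjusted p = 0.0367).

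SLC6A5, a marker of glycine-releasing neurons, had the largest rise at stage 6, from 22.6 ± 4.79 to 176 ± 38 CPM (2.96 ± 0.22, adjusted p = 1.2e-05). CACNA2D3 (2.91 ± 0.16), a calcium channel subunit gene, KRT17 (2.79 ± 0.36), an epithelial keratin, and CHODL (2.76 ± 0.28) followed. After these came the collagens COL24A1 (2.75 ± 0.18) and COL8A1 (2.73 ± 0.27), GNAS-AS1 (2.69 ± 0.18), GPR50 (2.57 ± 0.21), PRDM14 (2.49 ± 0.22) and the calcium-binding protein gene CALB2 (2.45 ± 0.42). GNAS-AS1 is an antisense partner of GNAS, and as no strand setting is given in the sources used here their reads cannot be told apart. AFP again had the largest fall (-3.64 ± 0.81, adjusted p = 0.00611), with 32.6 ± 41.1 CPM in controls, an SD above the mean. Without control replicate 3 its change was -1.79 (adjusted p = 0.0131), so its rank rested on that library. GABRP (-2.92 ± 0.28), CST1 (-2.83 ± 0.54), which is uncertain because the related CST4 is nearly identical, and 4 genes of stratified epithelium came next, COL17A1 (-2.83 ± 0.31), TP63 (-2.74 ± 0.35), SFN (-2.71 ± 0.36) and ABCA12 (-2.65 ± 0.34). CDC20B (-2.56 ± 0.33) and the brush border peptidase gene ANPEP (-2.37 ± 0.33) were also among the 10 largest falls. CST1 stood at -3.49 without transduced replicate 3.

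Islet lists were again higher in transduced cultures at stage 6. General neuronal genes, a list written after the tables were seen, rose too, for 17 of 20 (19 at stage 5). Counts of whole cultures do not tell which cells held the transcripts. Hormone granule and exocytosis genes rose for 19 of 21 with 2 not called, and for 21 when adjusted over the list alone (adjusted p = 2.11e-14), among them CADPS (1.47 ± 0.19), RAB3A (0.96 ± 0.13) and VAMP2 (0.74 ± 0.10). This and the other 9 lists called at stage 6 each had adjusted p = 0.380 with an estimated correlation. Of 12 beta cell identity genes 6 rose and 6 were not called, with 6 up adjusted over the list alone (adjusted p = 4.96e-05), GLP1R (1.22 ± 0.23), NPTX2 (0.96 ± 0.07) and ERO1B (0.95 ± 0.18) among them. Glucose sensing and excitability genes rose for 7 of 13 with 6 not called, 8 adjusted over the list alone (adjusted p = 0.000616), with ABCC8 at 1.47 ± 0.29 among the risers and SLC2A2 not called (-0.59 ± 0.39). In the list of other islet hormones and their regulators 4 rose, 1 fell and 5 were not called, equally so adjusted over the list alone (adjusted p = 0.0142). IRX1 (1.5 ± 0.21), IRX2 (0.73 ± 0.15), SST and HHEX rose and LOXL4 fell, and with Fisher's exact test the list was not called (adjusted p = 0.0766). Endocrine progenitor genes and NEUROG3 targets were not called as a list (3 up, 1 down of 13, with 4 and 1 adjusted over the list alone), with NEUROD1 at 1.24 ± 0.22, MYT1 at 0.75 ± 0.18 and INSM1 up and HES6 at -0.49 ± 0.10 down.

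Among other cell types at stage 6, neural genes rose for 6 of 13, fell for 1 and were not called for 6, with 8 up and 1 down adjusted over the list alone (adjusted p = 0.00619). ELAVL4 (1.02 ± 0.15) and DCX (0.80 ± 0.14) rose, and OTX2 (-1.2 ± 0.18), a forebrain and midbrain gene, fell. Enterochromaffin-like genes rose for 3 of 6, with 4 adjusted over the list alone (adjusted p = 0.00619), namely ADRA2A (1.89 ± 0.26), TAC1 (1.11 ± 0.22) and TPH1. The list was not called with Fisher's exact test (adjusted p = 0.0766). Liver genes fell for 7 of 11 with 4 not called, 8 adjusted over the list alone (adjusted p = 0.000482), FGG (-2.18 ± 0.35), FGA (-2.06 ± 0.38) and FGB (-1.94 ± 0.38) among them. Intestine and stomach genes fell for 4 of 7, 6 adjusted over the list alone (adjusted p = 0.000675), namely TFF3 (-1.82 ± 0.27), SOX21 (-0.93 ± 0.13), CDX2 and CLDN18. Proliferation genes fell for 12 of 20 and 8 were not called, with 18 down adjusted over the list alone (adjusted p = 1.74e-05), MCM5 (-0.43 ± 0.07) and MCM2 (-0.32 ± 0.06) being examples. In the Notch pathway 2 rose, 6 fell and 7 were not called of 15, equally so adjusted over the list alone (adjusted p = 0.00619), with DLL4 and HEYL up and NOTCH3 (-0.83 ± 0.10) and HES1 (-0.86 ± 0.08) among the genes that fell. Each of these lists also had adjusted p = 0.380 with an estimated correlation. Both measured acinar genes fell, 2 also adjusted over the list alone, PRSS1 by 2.19 and CEL by 1.02 on the log2 scale.

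The remaining lists were not called at stage 6. Pancreatic progenitor and duct genes gave 3 up and 5 down of 16 (4 and 7 adjusted over the list alone), with PROX1 (0.92 ± 0.11), ONECUT1 and ONECUT2 up and CFTR (-1.76 ± 0.24), HES1, FOXA1, KRT19 and MUC1 down. Pluripotency genes fell for 3 of 10 (3 adjusted over the list alone), namely SOX2 (-0.67 ± 0.12), DPPA4 (-0.74 ± 0.13) and ZFP42. Endothelial genes fell for 2 of 5 (2 adjusted over the list alone), TIE1 (-0.69 ± 0.15) and CLDN5 (-0.63 ± 0.14). Mesenchyme genes gave 1 up, THY1 (0.40 ± 0.10), and 3 down of 16, COL1A2 (-0.74 ± 0.18), COL5A1 and PDGFRB, equally so adjusted over the list alone. Endoplasmic reticulum stress genes gave 1 up (ASNS) and 7 down of 15 (2 and 7 adjusted over the list alone), with PDIA4 at -0.56 ± 0.10 and HSPA5 at -0.39 ± 0.07. This list was called with Fisher's exact test (adjusted p = 0.0118) and without control replicate 1 (0.0295). Genes usually kept low in beta cells gave 2 up and 4 down of 12 (3 and 5 adjusted over the list alone), with OAT (1.16 ± 0.07) and ACOT7 up and REST (-0.51 ± 0.07), SLC16A1, SMAD3 and MGST1 down. The p53 list had 1 up and 1 down, MDM2 (-0.40 ± 0.07), of 14, as it had adjusted over the list alone. Inflammatory genes rose for 1 of 4 (1 adjusted over the list alone), ICAM1, from 3.37 ± 0.534 to 17.1 ± 5.74 CPM (2.34 ± 0.22, adjusted p = 6.43e-05), and the list was called without transduced replicate 2 (adjusted p = 0.00917). Of 8 interferon and viral response genes 1 rose (1 adjusted over the list alone), IFI6 (1.18 ± 0.32, adjusted p = 0.0172), a call lost without transduced replicate 2 (0.74, adjusted p = 0.0872). RIGI was called without control replicate 3 (-0.47, adjusted p = 0.05 when rounded). The interferon list had a median of -0.06, a mean of 0.02 and a downward camera direction.

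At stage 6, 4925 genes were called, 2425 higher and 2500 lower in transduced cultures, and 303 in each direction differed by at least 2-fold. The authors' deposited table gave 2488 higher and 2608 lower. Without control replicate 2 the counts were 1496 higher and 1493 lower, and with the adjusted p held under 0.01 they were 1291 and 1272. The balance also turned toward higher genes with DESeq2's size factors (2768 higher and 2220 lower) and Wald test (3079 and 2532), in a fit of these 6 libraries alone (2813 and 2750), and without transduced replicate 2 (1843 and 1794) or 3 (1976 and 1890).

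**Figure D3:**
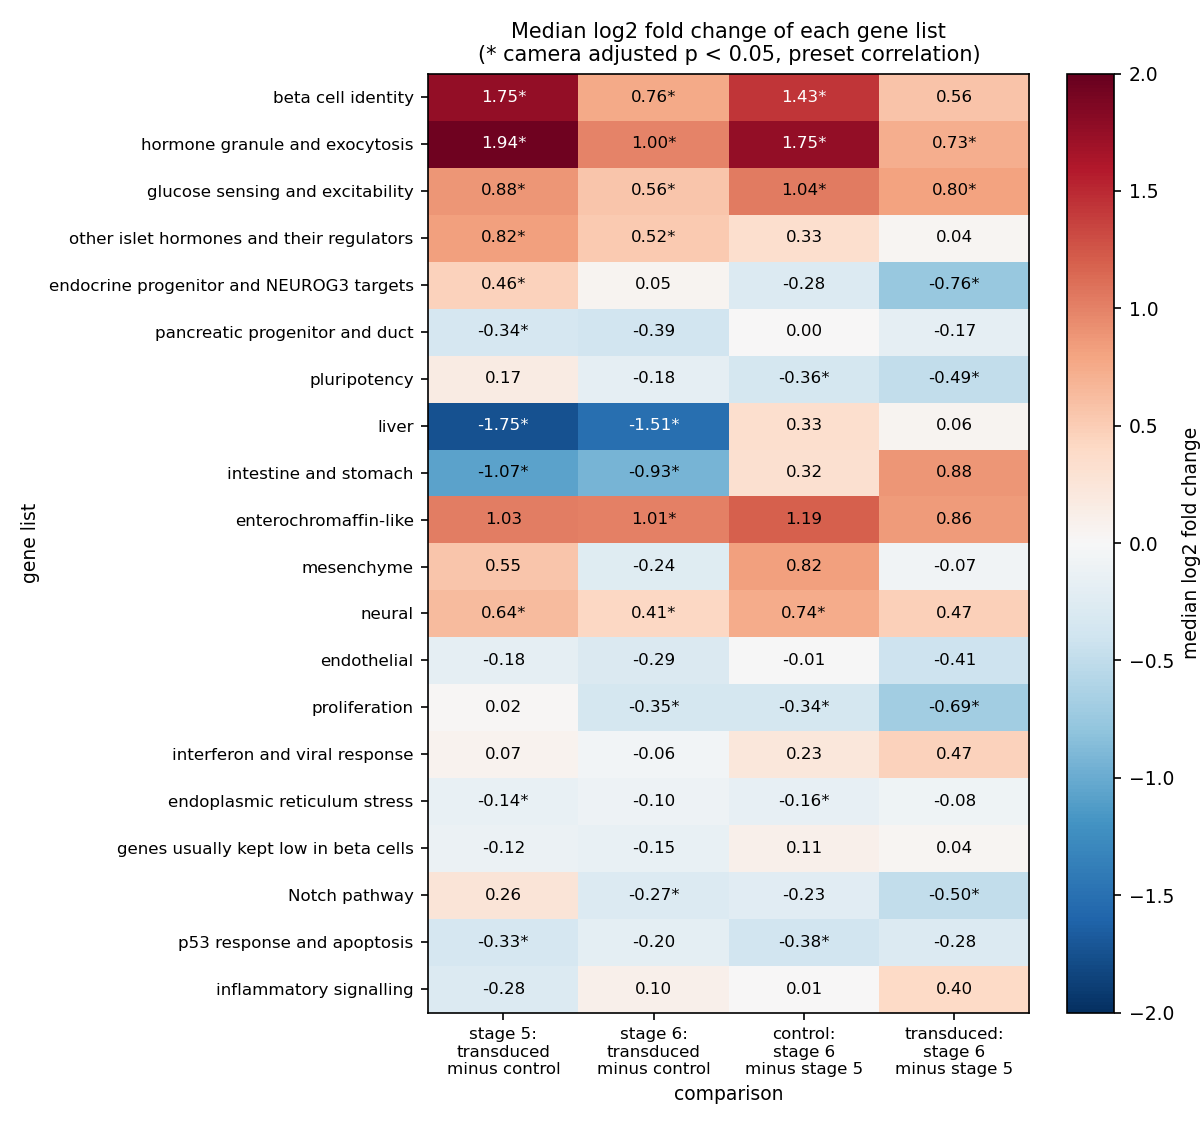
Median log2 fold change over the measured members of 20 gene lists (vertical axis) in 4 comparisons (horizontal axis), with colour running from blue (lower) to red (higher) and an asterisk where camera with its preset correlation of 0.01 gave an adjusted p under 0.05. The hormone granule and exocytosis list is higher in all 4 comparisons, with medians of 1.94, 0.996, 1.75 and 0.728, and with an estimated correlation none of the marked lists was called.

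The effects of transduction at both stages overlapped. They rest on different libraries and, by the protocol's order, on different sets of factors. Of the 17035 genes, 1546 were higher at both stages, where independent lists of the same sizes share 398.7, and 1195 were lower at both, against 310.2. Another 78 genes were called in opposite directions, against 712. Across genes, which are not independent, fold changes had Pearson's r 0.683 and Spearman's rho 0.657. The slope of stage 6 on stage 5, lowered by error at stage 5, was 0.54. SST, SLC6A5, CADPS and ELAVL4 rose at both stages, and FGB, FGG, AFP and PRSS1 fell at both. Tested directly as an interaction, the effect at stage 6 was lower in signed value than at stage 5 for 524 genes and higher for 223, and by size it was smaller for 502 of these and larger for 245. CHGA (-3.33 ± 0.64, adjusted p = 0.0124), GCG (-2.71 ± 0.67, adjusted p = 0.0414) and SST (-1.91 ± 0.19, adjusted p = 5.55e-04) were among the lower. CEMIP (4.24 ± 0.45, adjusted p = 6.48e-04) and ICAM1 (3.06 ± 0.32, adjusted p = 6.2e-04) were among the higher, and INS was not called (-2.85 ± 0.76, adjusted p = 0.0565). The call of GCG was lost in 9 of 12 fits that left out 1 library (adjusted p between 0.0545 and 0.109), and kept without stage 5 control replicate 3, stage 5 transduced replicate 2 or stage 6 control replicate 2. INS was called in 2 of these fits, without stage 5 control replicate 3 or stage 5 transduced replicate 2, and with the replicate number as a block within stage 5 (-2.99, adjusted p = 0.00533). With the adjusted p held under 0.01 the overlap counts were 808 and 515 and the interaction counts 174 lower and 54 higher, and DESeq2 called 745 lower and 538 higher interactions. Lower interactions numbered 314 without stage 5 control replicate 2, 274 without stage 5 control replicate 3, 327 without stage 6 control replicate 1 and 282 without stage 6 transduced replicate 3. Higher ones numbered 147 without stage 6 control replicate 1 and 137, 144 and 125 without stage 6 transduced replicates 1, 2 and 3.

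**Figure D4:**
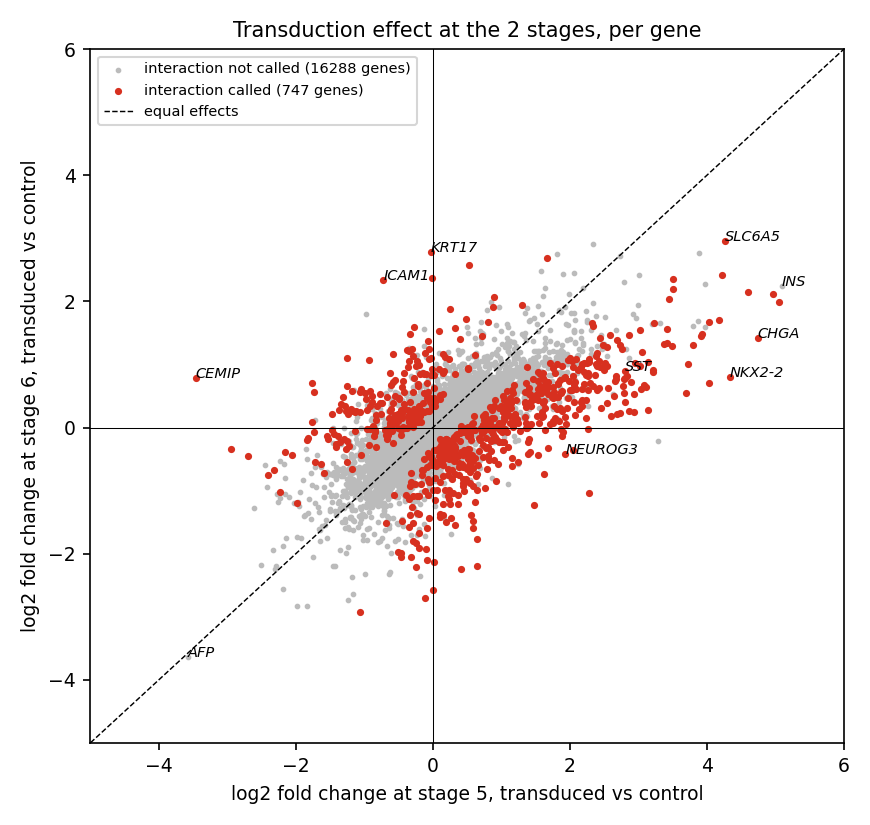
Log2 fold change of each of 17035 genes between transduced and control cultures at stage 5 (horizontal axis) and at stage 6 (vertical axis), 1 point per gene. The 747 called interactions are coloured apart, and the slope of 0.54 is lowered by error at stage 5.

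The control comparison asked how control cultures changed from stage 5 to stage 6. INS rose from 4.52 ± 3.98 to 58.9 ± 24.8 CPM (3.69 ± 0.59, adjusted p = 1.9e-04), GCG from 5.67 ± 4.27 to 170.5 ± 74.1 CPM (4.90 ± 0.55, adjusted p = 1.18e-05) and SST by 2.12 ± 0.14. Without stage 5 control replicate 3 the changes of INS and GCG were 4.68 and 5.7. NEUROG3 rose from 1.39 ± 0.287 to 12.3 ± 0.798 CPM (3.14 ± 0.42, adjusted p = 4.64e-05). PDX1 was not called (0.73 ± 0.38, adjusted p = 0.117), except in a fit of these 6 libraries alone (0.70, adjusted p = 0.0105), so 1 of 2 transduced factors rose, also when adjusted over the list alone. Largest among the rises were the developmental gene MAB21L2 (6.58 ± 0.32, adjusted p = 5.68e-08), the glutamate transporter gene SLC17A6 (5.16 ± 0.25), GCG, PCSK1 (4.87 ± 0.38) and the neuronal transcription factor gene PHOX2A (4.5 ± 0.27). The immediate early gene EGR1 had the largest fall, from 161 ± 27.4 to 4.18 ± 0.985 CPM (-5.27 ± 0.23, adjusted p = 2.7e-08), ahead of TRDC (-3.49 ± 0.19), CCN2 (-3.41 ± 0.21), ATF3 (-3.34 ± 0.14) and ANKRD1 (-3.20 ± 0.21).

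In controls all 21 hormone granule and exocytosis genes rose, 21 also adjusted over the list alone (adjusted p = 1.17e-12, and adjusted p = 0.490 with an estimated correlation), with UNC13A at 3.72 ± 0.27 and CPE at 1.60 ± 0.11. Of 12 beta cell identity genes 10 rose, among them PCSK1 and INS, and 2 fell, PAX6 among them, equally so adjusted over the list alone (adjusted p = 0.00231, and adjusted p = 0.717 with an estimated correlation). Glucose sensing and excitability genes gave 11 up, 1 down (SLC2A2) and 1 not called of 13, equally so adjusted over the list alone (adjusted p = 0.00577, and adjusted p = 0.717 with an estimated correlation), with SCN3A at 2.35 ± 0.20 and CACNA1A at 1.77 ± 0.16. Neural genes rose for 9 of 13, fell for 2 (SOX1 among them) and were not called for 2, with 10 and 2 adjusted over the list alone (adjusted p = 0.0296, and adjusted p = 0.717 with an estimated correlation), STMN2 (1.48 ± 0.19) and ELAVL4 (1.13 ± 0.15) being examples. Fisher's exact test did not call the neural list (adjusted p = 0.0504). Proliferation genes fell for 12 of 20, 12 adjusted over the list alone (adjusted p = 0.0073, and adjusted p = 0.717 with an estimated correlation), with CDC20 at -0.65 ± 0.09 and MCM2 at -0.47 ± 0.06. Pluripotency genes fell for 5 of 10, 5 adjusted over the list alone (adjusted p = 0.0402, and adjusted p = 0.490 with an estimated correlation), namely SALL4 (-1.43 ± 0.12), LIN28A (-1.03 ± 0.10), SOX2, DPPA4 and ZFP42. That call was lost without stage 5 control replicate 1 (0.0515) or stage 6 control replicate 2 (0.0579) and with Fisher's exact test (0.394). Endoplasmic reticulum stress genes gave 3 up (PDIA4, TRIB3 and CRELD2) and 6 down of 15, equally so adjusted over the list alone (adjusted p = 0.0419, and adjusted p = 0.717 with an estimated correlation), with ATF4 at -1.28 ± 0.08 beside ATF3. They were not called as a list without stage 5 control replicate 1 (0.0572), stage 6 control replicate 1 (0.0753) or stage 6 control replicate 3 (0.0564), nor with Fisher's exact test (0.569). The p53 list fell for 6 of 14, 6 adjusted over the list alone (adjusted p = 0.0137, and adjusted p = 0.717 with an estimated correlation), SESN2 (-1.0 ± 0.09) and MDM2 (-0.73 ± 0.07) among them. Fisher's exact test did not call it (0.479).

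The remaining lists were not called in controls, and their counts adjusted over the list alone are in brackets. Other islet hormones gave 5 up and 3 down of 10 (5 and 3), where LOXL4 (2.40 ± 0.17), GCG, SST and ETV1 were among those that rose and IRX1, IRX2 and HHEX fell. Endocrine progenitor genes gave 3 up and 6 down of 13 (4 and 6), where INSM1, MYT1 and ST18 rose and TOX3 (-1.22 ± 0.11) and ATOH8 (-1.08 ± 0.12) were among those that fell. Pancreatic progenitor genes gave 4 up and 5 down of 16 (4 and 4), with FOXA2, PROX1, MUC1 and SPP1 up and SOX9 (-1.54 ± 0.11), FOXA1, GATA4 and ONECUT1 among those down. Both acinar genes rose (2), PRSS1 by 1.75 ± 0.22 and CEL by 0.71 ± 0.18. Mesenchyme genes gave 10 up and 3 down of 16 (11 and 3), with LUM at 3.20 ± 0.53 up and TAGLN (-1.26 ± 0.14), VIM and PDGFRA down. Intestine and stomach genes gave 3 up and 1 down of 7 (3 and 1), with TFF3 (3.67 ± 0.30), CDX2 and CLDN18 up and SOX21 (-1.76 ± 0.13) down. Of 11 liver genes 1 rose (1), SERPINA1 (2.18 ± 0.59), with APOA1 at 0.80 ± 0.33 not called. SERPINA1 stood at 1.48 without stage 6 control replicate 3, and APOA1 was called without stage 5 control replicate 1 (1.04, adjusted p = 0.0329) and in a fit of these 6 libraries alone (0.76, 0.0218). Enterochromaffin-like genes gave 3 up and 1 down of 6 (3 and 1), with DDC (2.90 ± 0.37), TAC1 (1.79 ± 0.23) and TPH1 up and LMX1A down. Endothelial genes gave 1 up, TEK (1.48 ± 0.26), and 2 down, TIE1 (-2.0 ± 0.15) and CDH5, of 5 (2 and 2). The Notch pathway gave 2 up and 6 down of 15 (1 and 6), with JAG2 (1.77 ± 0.17) and HEY1 up and HEYL at -1.49 ± 0.17 among those down. Genes usually kept low in beta cells gave 2 up and 4 down of 12 (2 and 4), with HK1 (0.52 ± 0.09) and CAT up and REST (-0.46 ± 0.07), SLC16A1, PDGFRA and SMAD3 down. Interferon genes gave 2 up and 1 down of 8 (2 and 1), with IFIH1 (1.36 ± 0.30) and IFI6 up and IFIT1 (-1.59 ± 0.36) down. Of 4 inflammatory genes 1 rose (0 adjusted over the list alone), TNFAIP3 (0.40 ± 0.14, adjusted p = 0.0254), a call lost without stage 5 control replicate 3 (0.24, adjusted p = 0.147), stage 6 control replicate 2 (0.39, 0.0586) or stage 6 control replicate 3 (0.37, 0.0737). LIF stood at -0.37 ± 0.21. The median was above 0 and the camera direction downward for the pancreatic progenitor list (median 0.00, mean -0.07) and for genes usually kept low in beta cells (median 0.11, mean -0.00368).

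Between the stages 10352 genes were called in controls, 5545 higher and 4807 lower at stage 6, of which 1206 and 468 differed by at least 2-fold. The authors' deposited table, turned to stage 6 minus stage 5, gave 5536 higher and 4719 lower. The balance turned toward lower genes in a fit of these 6 libraries alone (5303 higher and 5318 lower), without stage 5 control replicate 3 (4614 and 4660), and among genes of at least 10 CPM in the higher group (3790 and 4252).

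In transduced cultures the same stage comparison asked what changed after stage 5. GCG rose from 75.2 ± 35 to 344 ± 103 CPM (2.19 ± 0.47, adjusted p = 0.00177), whereas INS (0.84 ± 0.51, adjusted p = 0.175) and SST (0.21 ± 0.13, adjusted p = 0.182) were not called. INS was called without stage 5 transduced replicate 3 (1.41, adjusted p = 0.0423). Neither PDX1 (-0.34 ± 0.36, adjusted p = 0.432) nor NEUROG3 (0.79 ± 0.38, adjusted p = 0.0892) was called. Thus edgeR called 0 of 2 transduced factors, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. NEUROG3 was called without stage 5 transduced replicate 3 (1.33, adjusted p = 0.00813). CEMIP (4.12 ± 0.35, adjusted p = 1.91e-06), MAB21L2 (4.11 ± 0.27), the lens crystallin gene CRYBB1 (3.95 ± 0.37), KRT17 (3.67 ± 0.37) and the proton pump gene ATP12A (3.46 ± 0.28) had the largest rises. EGR1 had the largest fall, from 225 ± 55.9 to 4.92 ± 0.276 CPM (-5.51 ± 0.23, adjusted p = 3.33e-08), ahead of FOS (-3.86 ± 0.33), VXN (-3.77 ± 0.25), TRDC (-3.71 ± 0.19) and NEUROG1 (-3.52 ± 0.12), a transcription factor gene of neural progenitors.

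Hormone granule and exocytosis genes rose for 17 of 21 in transduced cultures, 17 adjusted over the list alone (adjusted p = 0.000427, and adjusted p = 0.651 with an estimated correlation), with PCSK1N at 1.63 ± 0.20 and CPE at 0.95 ± 0.10. Glucose sensing and excitability genes rose for 9 of 13, 9 adjusted over the list alone (adjusted p = 0.0203, and adjusted p = 0.632 with an estimated correlation), with SCN3A at 1.42 ± 0.20 and CACNA1H at 0.69 ± 0.12. Endocrine progenitor genes and NEUROG3 targets gave 1 up (MYT1), 8 down and 4 not called of 13, equally so adjusted over the list alone (adjusted p = 0.00175, and adjusted p = 0.189 with an estimated correlation), with HES6 at -1.48 ± 0.10 and TOX3 at -1.31 ± 0.11. All 20 proliferation genes fell, 20 adjusted over the list alone (adjusted p = 6.91e-08, and adjusted p = 0.613 with an estimated correlation), CDC20 (-0.98 ± 0.09) and MCM2 (-0.68 ± 0.06) among them. Pluripotency genes fell for 6 of 10, 6 adjusted over the list alone (adjusted p = 0.00482, and adjusted p = 0.189 with an estimated correlation), with SALL4 at -1.51 ± 0.12 and DPPA4 at -1.48 ± 0.13. In the Notch pathway 1 (JAG2) rose and 9 fell of 15, equally so adjusted over the list alone (adjusted p = 0.00482, and adjusted p = 0.613 with an estimated correlation), DLL3 (-1.45 ± 0.16) and DLL4 (-1.43 ± 0.13) among the latter. With Fisher's exact test the endocrine progenitor (0.0914), pluripotency (0.187) and Notch (0.0776) lists were not called.

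The remaining lists had no call in transduced cultures, and their counts adjusted over the list alone are in brackets. Beta cell identity genes gave 5 up and 2 down of 12 (5 and 2), with SLC30A8 (0.98 ± 0.14), NKX6-1, PCSK1, ERO1B and NPTX2 up and PAX6 (-1.46 ± 0.18) among those down. Other islet hormones gave 2 up and 1 down of 10 (2 and 1), with GCG and LOXL4 (0.64 ± 0.16) up and ETV1 down. Neural genes gave 8 up and 2 down of 13 (8 and 2), with GAP43 (1.53 ± 0.23) among those up and SOX1 among those down. Pancreatic progenitor genes gave 2 up and 3 down of 16 (2 and 3), with FOXA2 and MUC1 up and SOX9 (-1.69 ± 0.11) and ONECUT1 among those down. Of the acinar genes PRSS1 rose by 1.84 ± 0.24 and CEL was not called (0.21 ± 0.18), the same adjusted over the list alone. Intestine and stomach genes gave 4 up and 1 down of 7 (4 and 1), with TFF3 (2.25 ± 0.29), CDX1, CDX2 and CLDN18 up and SOX21 (-2.18 ± 0.14) down. Enterochromaffin-like genes gave 3 up of 6 (3), namely TAC1 (3.0 ± 0.24), ADRA2A (0.92 ± 0.25) and TPH1. Mesenchyme genes gave 2 up and 3 down of 16 (2 and 3), with THY1 (0.48 ± 0.10) and COL1A2 up and TAGLN (-0.90 ± 0.14), VIM and PDGFRA down. Endothelial genes gave 2 up and 2 down of 5 (2 and 2), with KDR (1.65 ± 0.21) and TEK up and TIE1 (-2.06 ± 0.15) and CLDN5 down. Interferon genes gave 4 up and 1 down of 8 (4 and 1), with IFI6 (1.80 ± 0.33), IFIT1, MX1 and IFIH1 up and ISG15 (-0.65 ± 0.11) down. Inflammatory genes gave 2 up of 4 (2), ICAM1 (3.06 ± 0.23) and TNFAIP3 (0.65 ± 0.14). Endoplasmic reticulum stress genes gave 2 up and 6 down of 15 (2 and 6), with TRIB3 and CRELD2 up and ATF3 (-3.19 ± 0.14) and ATF4 (-1.28 ± 0.08) among those down. The p53 list gave 1 up (BBC3) and 6 down of 14 (1 and 6), with GADD45A at -1.18 ± 0.13 and SESN2 at -0.88 ± 0.09. Genes usually kept low in beta cells gave 4 up and 4 down of 12 (4 and 4), with OAT (0.67 ± 0.07), HK1, HK2 and CAT up and REST (-0.40 ± 0.07), SLC16A1, PDGFRA and SMAD3 down. Of 11 liver genes edgeR called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. It called APOA1 without stage 5 transduced replicate 2 (-0.98, adjusted p = 0.009) and RBP4 in a fit of these 6 libraries alone (1.17, 0.00515). The mesenchyme list had a median of -0.07, a mean of 0.02 and an upward camera direction.

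Between the stages 9941 genes were called in transduced cultures, 4870 higher and 5071 lower at stage 6, of which 820 and 459 differed by at least 2-fold. The authors' deposited table gave 4916 higher and 5013 lower. The balance turned toward higher genes with DESeq2's size factors (5186 higher and 4778 lower) and Wald test (5352 and 4886), in a fit of these 6 libraries alone (4556 and 4534), and without stage 5 transduced replicate 2 (4615 and 4428) or 3 (5141 and 4860). Lists that gained a call without a single library were those of endoplasmic reticulum stress (adjusted p = 0.0327 without stage 5 transduced replicate 2), p53 (0.0127 without stage 5 transduced replicate 3), enterochromaffin-like genes (0.0252 without stage 5 transduced replicate 3 and 0.0258 without stage 6 transduced replicate 1) and inflammatory signalling (0.0236 without stage 6 transduced replicate 2).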

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

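The tests of whether islet genes were lost in transduced cultures, of how controls changed between the stages, of the named genes with libraries left out, of the size of the effect after thinning, and of the splits with an offset or a block were chosen after the interaction was seen. The splits were first run without an offset, where mixing the arms widened the spread and 0 genes were called in each other split (at most 562 at an unadjusted p under 0.05), and the thinned counts were first read as lower interactions. Both versions were set aside after their results were seen.

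The effect of transduction differed between the stages for 747 genes by the interaction test of edgeR, being lower in signed value at stage 6 for 524 and higher for 223. By size the effect was smaller at stage 6 for 502 of them (371 lower, 131 higher) and larger for 245 (153 lower, 92 higher). SFN and GABRP were lower because they fell more at stage 6, and CEMIP, IFIT1, CSMD1 and KDR were higher because they had fallen at stage 5. Hormone and granule genes with a lower effect (log2 difference, adjusted p between 0.000338 and 0.0495 over the genes named in this paragraph) were CHGA (-3.33), PCSK1 (-3.32), SCG2 (-3.06), GCG (-2.71), SCGN (-2.45), UNC13A (-2.33), SST (-1.91), CADPS (-1.11), PCSK2 (-0.91) and CPE (-0.65). Islet and endocrine regulators with a lower effect were NKX2-2 (-3.53), NKX6-1 (-2.49), NEUROG3 (-2.35), ST18 (-1.76), ISL1 (-1.65), HES6 (-1.10), INSM1 (-0.99) and ETV1 (-0.74). Neural and developmental genes among them were BHLHE22 (-2.85), MAB21L2 (-2.47), SLC17A6 (-2.40), NEUROG1 (-1.80), VXN (-1.69), PHOX2A (-1.48), SLC6A5 (-1.30) and CACNA1A (-0.94), and others were LUM (-3.32), SFN (-2.58), CRYBA2 (-2.47), COL3A1 (-2.42), DDC (-2.41), GABRP (-1.86), SYNPO (-1.80), LOXL4 (-1.76), CLDN5 (-1.08), DPPA4 (-1.06), DLL4 (-0.96) and NPTX2 (-0.42). A higher effect at stage 6 was found for CEMIP (4.24), ICAM1 (3.06), KRT17 (2.81), IFIT1 (2.61), ATP12A (2.47), CSMD1 (2.26), GPR50 (2.04), KDR (1.67), NFIA (1.65), ANKRD1 (1.32), GNAS-AS1 (1.03) and OAT (0.54). Of these 50 genes, 30 kept the call in all 12 fits that left out 1 library. The calls of ANKRD1, CACNA1A, CADPS, COL3A1, CPE, CRYBA2, DDC, ETV1, GCG, GNAS-AS1, INSM1, LUM, NEUROG3, NFIA, NPTX2, PCSK2, PHOX2A, SCGN, SLC6A5 and SYNPO were each lost in 1 to 10 of them (adjusted p between 0.0501 and 0.151), and each of the 12 libraries ended at least 1 of these calls when left out. With the replicate number as a block within stage 5, SLC6A5 (0.0501) and CRYBA2 (0.05 when rounded) lost the call. The counts moved by over 1.5 times without single libraries, to 314 lower without stage 5 control replicate 2, 274 without stage 5 control replicate 3, 327 lower and 147 higher without stage 6 control replicate 1, 137 and 144 higher without stage 6 transduced replicates 1 and 2, and 282 lower and 125 higher without replicate 3.

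Of the gene lists, 10 differed between the stages by camera with its preset correlation, and none was called with an estimated correlation. The median interaction was -1.09 for beta cell identity (adjusted p = 1.73e-08, and adjusted p = 0.155 with an estimated correlation), where 6 of 12 members were called lower and 1 higher, with 7 and 1 adjusted over the list alone. It was -0.91 for hormone granule and exocytosis (3.49e-15, estimated 0.155; 10 of 21 lower, 14 adjusted over the list alone) and -0.73 for other islet hormones (0.00103, estimated 0.155), where GCG, SST, ETV1 and LOXL4 were among the lower and HHEX higher, with 6 and 2 adjusted over the list alone. Endocrine progenitor genes had -0.59 (2.7e-05, estimated 0.116), with INSM1, ST18 and HES6 lower and 6 adjusted over the list alone, and the Notch pathway -0.64 (0.000405, estimated 0.198), with NOTCH1, JAG1 and DLL4 lower and 7 adjusted over the list alone. Neural genes had -0.48 (0.00553, estimated 0.534) with 0 of 13 called by edgeR, 6 lower at an unadjusted p under 0.05 and 4 by DESeq2, and 4 adjusted over the list alone. Proliferation genes had -0.36 (3.15e-06, estimated 0.502) with 0 of 20 called, 12 lower unadjusted, 5 by DESeq2 and 8 adjusted over the list alone. Inflammatory signalling had 0.38 (0.000405, estimated 0.155) with ICAM1 alone called, also adjusted over the list alone, and mesenchyme -0.33 (0.019, estimated 0.642) with COL3A1, COL6A3 and LUM lower and 7 adjusted over the list alone. The mesenchyme call was lost without stage 5 transduced replicate 1 (0.134), stage 6 control replicate 3 (0.0771) or stage 6 transduced replicate 2 (0.0972). The p53 list had 0.21 (0.0297, estimated 0.642) with 0 of 14 called, 2 higher unadjusted, 2 by DESeq2 and 1 adjusted over the list alone. It lost its call without stage 5 control replicate 1 (0.108), stage 5 transduced replicate 3 (0.394), stage 6 control replicates 1 (0.0869) and 3 (0.11) or stage 6 transduced replicates 1 (0.0667) and 3 (0.0651). Fisher's exact test called neither the neural, proliferation and p53 lists (adjusted p = 1 for each) nor inflammatory signalling (0.147). Glucose sensing and excitability genes (median -0.40) were called lower without stage 5 transduced replicate 2 (0.00719) and not with all libraries (0.174). Among lists that were not called, the median, the mean and the camera direction differed in sign for the pancreatic progenitor (0.04, -0.00447, up), liver (-0.24, -0.24, up), intestine and stomach (0.16, -0.10, down), enterochromaffin-like (0.37, -0.27, up), endothelial (-0.05, 0.12, up) and interferon (-0.03, 0.33, up) lists.

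The number of called interactions was compared with other splits of the libraries that exchanged 1 library per stage between the arms, with each gene's mean transduction effect held as an offset. In 1 of 60 splits drawn from 82 were as many genes called, the real one with 747, while the others called at most 10 and averaged 1061 at an unadjusted p under 0.05. Of the 60, 39 break stage 5 pairs, and the 21 that part all 3 pairs, the real one included, called at most 0 otherwise (812 on average unadjusted). All 28 splits that part the stage 5 pairs in this way were therefore also fitted with the replicate number as a block within stage 5. In 1 of them, the real one with 949, were as many genes called, and the others called at most 2 and averaged 1080 unadjusted. Given the stage 5 pairing, which was read from these data, only the blocked fits argue against chance between these libraries. Chance between cultures cannot be excluded, since the replicates may be technical.

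The smaller effect at stage 6, found by size in 502 of the 747 genes, was weighed against technical causes. After every library was thinned to the smallest total, 503 of 750 called interactions had the smaller effect at stage 6, and 482 of these were among the 502, but transduced libraries were 1.11 times as deep as controls at each stage, so thinning had little to move and decides nothing. A loss in transduced cultures between the stages is argued against for hormone granule genes (median change 0.728, SE 0.0798) and stays open for endocrine progenitor genes (-0.761, SE 0.208). The SEs in this paragraph come from the spread over the members of a list, not from the spread between libraries. Members of a list are not independent replicates. For beta cell identity (0.563, SE 0.245, quartiles -0.207 and 0.983) and other islet hormones (0.0378, SE 0.255, quartiles -0.2 and 0.602) members went both ways, so nothing is decided. A difference in the factors received was not tested and cannot be told apart from the stage, as MAFA is given at stage 6. For hormone granule genes a larger rise in controls (median 1.75, 21 of 21 called) than in transduced cultures (0.728, 17 of 21) restates the interaction. Across all genes it stays open that controls may have changed between the stages in part as transduction had changed stage 5 cultures. The covariance across genes of these 2 changes was 0.156, against 0.0105 in simulated unchanged groups sharing the stage 5 controls, a difference of 0.146.

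Both of those comparisons share the stage 5 control libraries, so their correlation of 0.459 (0.501 in the simulated groups) is not evidence of a shared effect, and 3 controls are too few to divide. Of the genes, 1829 were higher in both, where independent lists would share 911.7, and 806 were lower in both against 596.5, and part of each excess may come from the shared controls, for which the simulated covariance was taken off to give 0.146.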

How the results depend on the processing

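The 10 CPM minimum, the block within stage 5, the further fits of the interaction and the overlap, and the list tests with single libraries left out were chosen after seeing the data. No call of a named gene or list reversed. The balance of higher and lower counts turned round at stage 5 in 4 of 6 fits that left out 1 library, at stage 6 with DESeq2's size factors (2768 and 2220), its Wald test (3079 and 2532), the 2 groups alone (2813 and 2750), an adjusted p of 0.01 and without control replicate 2 (1496 and 1493), transduced replicate 2 (1843 and 1794) or 3 (1976 and 1890). In transduced cultures it turned with DESeq2's size factors (5186 and 4778), its Wald test (5352 and 4886), the 2 groups alone (4556 and 4534), at least 2-fold and without stage 5 replicates 2 (4615 and 4428) or 3 (5141 and 4860), and in controls with the 10 CPM minimum (3790 and 4252), the 2 groups alone (5303 and 5318) and without stage 5 replicate 3 (4614 and 4660). The cause of each move was not tested except where fewer genes or libraries account for it. With an adjusted p of 0.01 the counts higher and lower were 1788 and 1125 at stage 5, 1291 and 1272 at stage 6, 54 and 174 in the interaction, and 808 and 515 in the overlap. With at least 2-fold they were 717 and 295, 303 and 303, 99 and 300, and 208 and 111, with 820 and 459 in transduced cultures and 1206 and 468 in controls. DESeq2 called 538 higher interactions, moving the share of higher calls from 29.9% to 41.9%. With an estimated correlation camera called 0 lists up and 0 down in each comparison. Fisher's exact test called 1 list down in each stage comparison and 0 up in the interaction. Leaving out 1 library gave 1875 to 2646 higher and 1617 to 2424 lower at stage 5, 1496 to 2167 and 1493 to 2230 at stage 6, with the lowest without control replicate 2, 125 to 325 and 274 to 521 in the interaction, and 1101 to 1488 and 861 to 1221 in the overlap. In transduced cultures it gave 4302 to 5141 and 4428 to 4860, and in controls 4614 to 5109 and 4181 to 4876. Lists called down at stage 5 fell from 5 to 2 without control replicate 1 or transduced replicate 2, those in controls from 4 to 2 without stage 5 control replicate 1, and those called up in the interaction from 2 to 1 without stage 5 control replicate 1, stage 5 transduced replicate 3, stage 6 control replicates 1 and 3 or stage 6 transduced replicates 1 and 3. Of 233 calls of named genes, 227 held with each library left out. With the replicate number as a block the counts were 2660 and 2029 at stage 5, 2312 and 2443 at stage 6, 4836 and 5023 in transduced cultures, 5512 and 4770 in controls, 203 and 459 in the interaction, and 1476 and 1174 in the overlap. Under the block CEL at stage 5 was not called (0.0627), whereas GCG (0.0214) and RIGI (0.0405) at stage 6, INS in transduced cultures (0.043) and their endoplasmic reticulum stress list (0.0408) were. Outside stage 5 the numbers were treated as names only, as 0 of 3 same-numbered pairs in each comparison had correlated deviations over 0.1 (-0.192 to 0.00316). Same-numbered libraries of opposite arm and stage, which no comparison pairs, ranged from -0.191 to 0.209. In all, 6 of 18 same-numbered pairs lay over 0.1, and over all libraries 6 of 12 matched their own number best. With a block within stage 5 only, where the numbers were taken to pair the libraries, 2943 and 2419 genes were higher and lower at stage 5. The counts were then 324 and 625 in the interaction and 1565 and 1281 in the overlap. That block ended the stage 5 call of CEL (0.0543), called the enterochromaffin-like list (0.0364), ended 2 of 50 calls of named interactions and made 8, and changed no other call of a named gene or list at stage 5. No low-count filter and a minimum count of 100 removed 0 genes, so they test nothing, for lists as well. A pseudocount and an adjustment of the authors' p-values do not apply to counts, and the 10 CPM minimum was not run for lists. Depth limits mainly genes near 1 CPM.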

Other observations

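The 9 gene lists in this part were written after the tables had been seen, so their tests describe these libraries only, and the tests of neuron shares, of handling and of dividing cells were also chosen after their results were seen.

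Genes of inhibitory interneurons of hindbrain and spinal cord rose in transduced cultures at both stages. Of 15 measured, 13 rose at stage 5 (median 2.25, adjusted p = 0.0188 with an estimated correlation) and 13 at stage 6 (1.70, adjusted p = 0.0168 with an estimated correlation). The list was picked partly from genes seen to change, so these p-values are no independent evidence of the rise. LBX1 went from 36 ± 13.2 to 110.3 ± 26.2 CPM at stage 6 (1.61 ± 0.41, adjusted p = 0.0114). PAX2 went from 18.2 ± 7.5 to 83.1 ± 13.8 CPM (2.20 ± 0.24, adjusted p = 1.28e-04). GAD1, which makes the transmitter GABA and is also expressed in islets, went from 4.82 ± 0.612 to 23.8 ± 4.82 CPM. TFAP2B, an abundant member with 216 ± 51.8 CPM in controls and 169.6 ± 21.1 CPM in transduced cultures at stage 6, did not pass the test at either stage (-0.11 ± 0.17 and -0.35 ± 0.17). LBX1 overlaps the antisense gene LBX1-AS1, so its reads are uncertain. General neuronal genes rose for 19 and 17 of 20 (0.0541 and 0.106 with an estimated correlation). Excitatory neuron genes rose for 8 and 5 of 11 (0.0548 and 0.138) and HOX genes, which mark hindbrain and spinal position, for 8 and 12 of 14 (0.418 and 0.106).

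Neural crest and glial genes fell at stage 6 for 9 of 11 and rose for 1 (median -1.22, adjusted p = 0.0226 with an estimated correlation), and the interaction was lower for 8 (0.0197). SOX10 went from 30.5 ± 4 to 6.55 ± 1.46 CPM (-2.22 ± 0.20, adjusted p = 5.19e-05) and was not called at stage 5 (-0.25 ± 0.19). Genes of stratified epithelium fell for 10 of 18 at stage 5 and 15 at stage 6 (0.394 and 0.0877 with an estimated correlation), with LAMB3 at -1.80 ± 0.37 and AQP3 at -2.10 ± 0.25 at stage 6, where KRT17 alone rose (2.79 ± 0.36). Dorsal neural progenitor genes were lower at stage 6 than at stage 5 for 12 of 12 in controls (0.0154) and 8 of 12 in transduced cultures (0.0202), with PAX3 at -2.56 ± 0.14 and -2.50 ± 0.14 and OLIG3 at -2.84 ± 0.12 and -2.85 ± 0.13. Metallothionein and zinc response genes fell for 5 of 6 in transduced cultures (0.0202) and 3 of 6 in controls (0.112), with 1 rising in each, with the zinc exporter gene SLC30A1 at -2.99 ± 0.09 and -2.76 ± 0.09.

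The interneuron genes may have risen because transduced cultures held a larger share of all neurons. Excitatory genes then rise as general neuronal genes do, and their medians differed by 0.125 at stage 5 (permutation p = 0.894, adjusted 0.894) and by 0.116 at stage 6 (0.455, adjusted 0.682), so this stays open. An earlier test set interneuron against general neuronal genes (0.767 at stage 5, permutation p = 0.0292; 0.893 at stage 6, 9e-05) and was set aside after its result was seen, because the interneuron list was picked partly from genes seen to change. The replacement and its rule were written after its own values were seen, and 10 of the 20 general neuronal genes also stand in fixed lists. Islet cells as the source cannot be told apart, since across 12 libraries the deviations of 22 islet and 15 interneuron genes from their group means had r = 0.291 (permutation p = 0.537), rho = 0.357 (0.363) and r = 0.363 without the 2 farthest libraries.

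Immediate early genes, which respond within minutes to stimulation, fell from stage 5 to stage 6 for 22 of 22 in controls (adjusted p = 0.0108 with an estimated correlation) and 21 of 22 in transduced cultures (0.0118), with EGR1 at -5.27 ± 0.23 and -5.51 ± 0.23 and CCN1 at -2.71 ± 0.21 and -2.72 ± 0.21. Fewer dividing cells could lower such genes, and in controls their median change minus that of the proliferation list was -1.43, but the list was written after these falls had been seen, so this decides nothing and stays open. Handling or harvest that differed between the stages cannot be told apart from the stage, because 21 of the genes were lower in both arms and each stage has its own libraries.

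With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits of the 6 libraries alone edgeR called 3660 genes in the real split at stage 5 and at most 0 otherwise (561 at an unadjusted p under 0.05). The numbers were 5563 and 0 (379) at stage 6, 9090 and 0 (334) in transduced cultures, and 10621 and 0 (391) in controls. Other splits mix the groups, which widens the spread, so 0 calls there decide nothing. At stage 5, with equal numbers taken as pairs, 4 of the 10 splits part all 3 pairs. Those but the real one called at most 0 (286 unadjusted), and the 6 others part 1 pair each.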
